A study of Mus musculus with 12 samples.

How the data were processed

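RNA was measured in thymic tissue of mice by sequencing of poly(A) RNA. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a directional kit that keeps strand, and sequencing was done on an Illumina HiSeq instrument. There were 12 libraries in 4 groups of 3: control thymic tissue, thymic lymphomas with the MYC mutant T58A, thymic lymphomas with the mutant S62A, and thymic masses of S62A animals with splenomegaly. Groups were taken from the labels, and replicate numbers follow the order of deposit and pair nothing. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

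For each library the authors deposited whole-number read counts per RefSeq transcript, not normalized. The authors also deposited FPKM values, which are reads scaled to transcript length and to the reads of the library. Per the submitters' processing notes, the tools included bcl2fastq 2.20.0.422, Bowtie 1.0.0 and DESeq2, with genome build mm9. The version of DESeq2, the counting tool, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Positions are those of the authors' files on mm9. Their starts were assumed to be counted from 0 and are printed counted from 1; a test of this through the lengths implied by the FPKM values left it open.

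The tables list 36141 transcripts of 24478 gene symbols, of which 6148 have several transcripts. Transcripts of a gene mostly held nearly the same reads: among 4131 such symbols with at least 500 reads, the smallest transcript total was a median 0.988 of the largest. The value of a gene was therefore the transcript with the most reads over all libraries. In 30 genes with at least 100 reads the counts equalled those of another symbol in every library. Genes of families with near-identical copies, and genes that overlap on opposite strands, remain uncertain, because the way reads were shared among them is not given. No rows of T cell receptor segments, immunoglobulin segments or mitochondrial genes were used here, so the planned measure of receptor segment dominance was not run.

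Summed over genes, depth ranged from 9577373 to 22437969 reads. A gene at 0 reads in a group was given a floor of 3 counts over the 3 libraries together, and its fold is stated as a lower bound. With 1 to 3 reads in a group, the ratio is given with an exact 95% counting interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

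Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group with its minimum count of 10, which left 15606. Libraries were scaled by TMM factors, and a quasi-likelihood model (glmQLFit, glmQLFTest) with group as the only term was fitted to all 12 libraries, so that the groups shared the estimate of the spread. P-values were adjusted by the method of Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05. Errors are standard errors (SE) for log2 fold changes and standard deviations (SD) for CPM, the reads of a gene scaled to the depth of its library, with 3 libraries in each group throughout. No SE is given for genes at 0 reads in a group.

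The 5 comparisons, the tests, the rule for the genes named, 36 gene lists and the main set of alternatives were chosen before the data were examined. The rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold. Such genes needed a mean of at least 20 CPM in either group, no overlap between the groups' libraries, and a symbol that was neither a predicted gene nor a receptor segment. It added Myc and, per list, the 2 risen and the 2 fallen members with the smallest adjusted p. The results of 2 genes that the rule named are not reported here.

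The lists of processes were MYC family and partners, regulators of MYC stability, ribosome biogenesis, nucleotide synthesis, glycolysis and lactate, amino acid and one-carbon metabolism, DNA replication, mitosis, DNA damage repair, p53 target genes, BCL2 family, ARF and CDK inhibitor genes, Notch target genes, interferon response, antigen presentation, immune checkpoint and cytotoxic genes, TGF-beta and extracellular matrix, and immediate early genes. The lists of cell types were pan T cell, double-positive thymocyte, early double-negative thymocyte, mature T cell, B cell, immature B cell, plasma cell and germinal centre, macrophage and monocyte, granulocyte, dendritic cell, natural killer cell, thymic epithelium, fibroblast, endothelium, adipocyte, erythroid, megakaryocyte and platelet, and skeletal muscle. Some genes stand in several lists, such as Rag1 and Rag2 in those of double-positive thymocytes and immature B cells. Because the tissue is a mixture, a list of markers reads the cells and the expression per cell together.

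Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over 180 tests, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. Calls of members are given over all genes tested and adjusted over the list alone. A further 4 lists were drawn up after the data were examined: Wnt and beta-catenin targets, imprinted genes, lymph node stroma and high endothelium, and unfolded protein response and secretion.

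Alternatives were size factors of the DESeq2 kind, library size only, other filters, DESeq2 1.42.0, limma voom with sample weights, fits to the 6 libraries compared, removal of immunoglobulin and haemoglobin genes, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with and without a filter, libraries of 1 title code only, and each library left out in turn. Chosen after seeing the data were the mean of a gene's transcripts, removal of the ribosomal RNA gene Rn45s, removal of the 50 most abundant genes, and removal of T58A lymphomas 1 and 2.

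Tests were tried on counts simulated from the libraries' means and depths, with 50 changed genes at each of 4 folds. For T58A lymphoma against control, edgeR called 70% of 4-fold and 32% of 2-fold rises, with 4 false calls among 15283 genes. For S62A against T58A lymphoma it called 68% and 30%, with 3 false calls among 15255. Camera called all changed lists in both. Unequal group spread and correlated genes were not tested, so the data may hold more false calls.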

Results

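Poly(A) RNA of thymic tissue was compared among 12 libraries of mice, 3 in each of 4 groups. Control tissue was labelled as T lymphocytes with endogenous MYC only. Lymphomas of the thymus were labelled as T lymphocytes with an ectopic MYC mutant only, T58A or S62A, in which alanine replaces a threonine or a serine whose phosphorylation governs turnover of the MYC protein. The remaining group was the thymic mass of S62A animals with splenomegaly, labelled as T and B lymphocytes with ectopic S62A and endogenous MYC. Reads assigned to genes came to 18545674, 17339406 and 22437969 in the control libraries and 17192070, 18376634 and 16830893 in T58A lymphomas. They came to 16258508, 14172274 and 15409907 in S62A lymphomas and 19905444, 9577373 and 14890182 in splenomegaly masses.

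Libraries of a group differed by more than sampling noise. The chi-square per degree of freedom over genes ran from 2.8 between controls 1 and 2 to 123 between S62A lymphomas 1 and 3, and control 3 stood at 46.6 and 43.4 from controls 1 and 2. Each library was counted as a replicate by its label, which this spread does not test. Biological variation, estimated within each group, was 17.2% in controls, 41.1% in T58A lymphomas, 45% in S62A lymphomas and 28% in splenomegaly masses. The shared estimate used in the tests is therefore small for lymphomas and large for controls. Along the first principal component, with 39.3% of the variance, splenomegaly masses lay between −132 and −121.5 and lymphomas between 26.1 and 88.9. Along the second, with 31.8%, controls lay between 121.8 and 124.4 and all other libraries at −11.5 or lower.

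The labels tie the groups to MYC, so the Myc gene was examined before all others. Myc (NM_001177352, chromosome 15 from 61816896 to 61821916, mm9) stood at 82.8 ± 2.82 CPM (SD, n = 3) in control tissue. It rose to 143 ± 13.4 CPM in T58A lymphomas, a log2 fold change of 0.79 ± 0.13 (SE, adjusted p = 0.000876), and to 173 ± 26.1 CPM in S62A lymphomas (1.06 ± 0.13, adjusted p = 0.000109). Splenomegaly masses held 91.9 ± 7.89 CPM, which did not pass the test against control (0.15 ± 0.13, adjusted p = 0.347) and was lower than in S62A lymphomas (−0.91 ± 0.13, adjusted p = 0.000172). Between the lymphoma groups the Myc difference did not pass the test (0.27 ± 0.13, adjusted p = 0.225). Mycn, the MYC paralog of early development, fell from 11.3 ± 2.52 CPM to 0.132 ± 0.146 in T58A lymphomas, 0.112 ± 0.0765 in S62A lymphomas and 0.317 ± 0.107 in splenomegaly masses, with adjusted p-values of 0.000158, 0.000108 and 0.000193. The value of Myc counts reads assigned to the mouse gene, and reads of the ectopic copy were not told apart from those of the endogenous gene. With the libraries of title code H only, control 3 against the 3 T58A lymphomas, the Myc difference was 0.79, and the lone control gives no spread of its own.

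**Figure D1:**
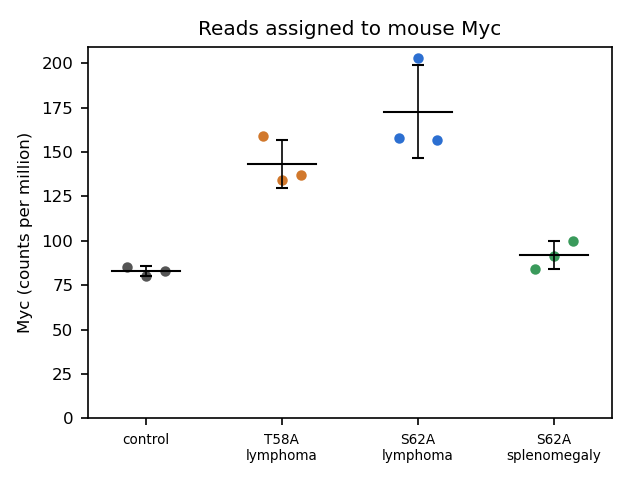
CPM of Myc in each of the 12 libraries (points), with the mean and SD of each group of 3. Control libraries lie between 79.9 and 85.5 CPM, splenomegaly masses between 84.2 and 100, and both lymphoma groups between 134 and 203.

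T58A lymphomas were set against control thymic tissue. Genes of thymic epithelium and of double-positive thymocytes stood far lower in the lymphomas, and genes of ribosome assembly and of macrophages stood higher. Ccl25, the chemokine with which thymic epithelium attracts thymocyte progenitors (chromosome 8 from 4349588 to 4360020), fell from 668 ± 38.3 CPM to 3.15 ± 0.929 (log2 fold change −7.72 ± 0.31, adjusted p = 3.09e-07). Ptcra, the invariant chain of the pre-T cell receptor, had no reads in any T58A lymphoma against 57.6 ± 5.73 CPM in controls and was at least 1020-fold lower (adjusted p = 2.91e-06). Itgam, an integrin chain of myeloid cells, rose from 11.9 ± 0.618 to 579 ± 286 CPM (5.6 ± 0.53, adjusted p = 3.6e-05). The macrophage median was 1.61, so Itgam was atypical.

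Among the largest rises, Notum, a secreted enzyme that inactivates Wnt proteins (chromosome 11 from 120515103 to 120522151), rose by 8.8 ± 0.63 on the log2 scale, from 0.352 ± 0.164 to 163 ± 117 CPM. Sp5, a transcription factor induced by Wnt signals, rose by 8.58 ± 0.68 and Prox1, a homeobox factor of lymphatic endothelium, liver and lens, by 8.18 ± 0.7. Peg10, an imprinted gene derived from a retrotransposon, rose from 0.468 ± 0.335 to 489 ± 129 CPM (adjusted p = 0.000484). The limb factor gene Tbx4 and the placental homeobox gene Esx1 rose by 9.23 ± 0.83 and 10.29 ± 1.22. Among the largest falls were Psmb11, the catalytic subunit of the thymoproteasome of cortical epithelium, at −11.12 ± 0.67, and Prss16, a serine protease of the same cells, at −9.45 ± 0.66.

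Of the 29 ribosome biogenesis genes measured, 25 rose in T58A lymphomas (25 adjusted over the list alone) and 4 did not pass, with a median log2 fold change of 1.14. Rrp12 rose by 1.92 ± 0.14 and Pes1 by 1.17 ± 0.1. The list was called by camera (adjusted p = 1.84e-17), with adjusted p = 0.175 with an estimated correlation. Amino acid and one-carbon metabolism followed, with 11 of 19 members up and 3 down (13 and 3 adjusted over the list alone). Slc7a5, a transporter of large neutral amino acids, rose by 2.61 ± 0.23, and Pycr1, an enzyme of proline synthesis, rose from 0.426 ± 0.173 to 38.6 ± 17.9 CPM. Its median was 0.88 and its adjusted p = 0.000222, with adjusted p = 0.293 with an estimated correlation. In the list of TGF-beta and extracellular matrix 10 of 20 members rose (11 adjusted over the list alone), among them Thbs1 (3.75 ± 0.47) and Fn1 (2.67 ± 0.38). The median was 1.57 and the adjusted p = 0.000684, with adjusted p = 0.518 with an estimated correlation.

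Notch target genes fell, with 10 of 16 members down (11 adjusted over the list alone), a median of −1.3 and an adjusted p of 2.64e-06, with adjusted p = 0.22 with an estimated correlation. Notch1 itself, a receptor needed for T cell commitment, fell from 282 ± 50.2 to 18.3 ± 1.71 CPM (−3.94 ± 0.24). Interferon response genes had 8 of 26 members down and 2 up (8 and 2 adjusted over the list alone). The median was −0.93 (adjusted p = 0.0121, and adjusted p = 0.662 with an estimated correlation). Stat2, a mediator of type I interferon signals, fell by 1.22 ± 0.19. Antigen presentation genes had 6 of 18 members down and 1 up (6 and 1 adjusted over the list alone). The median was −0.54 (adjusted p = 0.00689, and adjusted p = 0.654 with an estimated correlation). Tap2, a peptide transporter, fell by 1.86 ± 0.17, while Ctss, a protease of antigen-presenting cells, rose by 1.96 ± 0.32. Both calls were lost without T58A lymphoma 3, where the interferon list had a median of −0.67 (adjusted p = 0.182) and the antigen presentation list −0.15 (adjusted p = 0.106). Of the immediate early genes, which respond within minutes to stimulation or tissue handling, 7 of 17 fell and 1 rose (9 and 1 adjusted over the list alone), with Egr1 at −1.98 ± 0.25. The median was −0.51 (adjusted p = 0.0366, and adjusted p = 0.541 with an estimated correlation). That call was lost without T58A lymphoma 2 (−0.65, adjusted p = 0.0843) or 3 (−0.37, adjusted p = 0.0994).

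Markers of cell types moved at the same time. Pan T cell genes had 11 of 17 members down (14 adjusted over the list alone). The median was −1.44 (adjusted p = 1.19e-06, and adjusted p = 0.341 with an estimated correlation). Cd247, the zeta chain of the T cell receptor complex, fell by 2.92 ± 0.17, and Lck, its proximal kinase, fell from 2360 ± 73.6 to 664 ± 97.6 CPM. Of 20 double-positive thymocyte genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), the riser being Endou (1.11 ± 0.27). Their median was −1.49 (adjusted p = 1.4e-07, and adjusted p = 0.131 with an estimated correlation). Mature T cell genes had 6 of 18 members down and 1 up (6 and 1 adjusted over the list alone), with Ikzf2 at −3.39 ± 0.32. The median was −1.06 (adjusted p = 0.00382, and adjusted p = 0.502 with an estimated correlation). Immature B cell genes had 6 of 12 members down (6 adjusted over the list alone). The median was −1.45 (adjusted p = 0.0137, and adjusted p = 0.292 with an estimated correlation). The members that fell include Rag2 (−3.89 ± 0.58) and Bach2 (−2.62 ± 0.4), which thymocytes also express.

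Thymic epithelium genes fell in 13 of 20 members (14 adjusted over the list alone). The median was −2.56 (adjusted p = 9.54e-15, and adjusted p = 0.131 with an estimated correlation). Macrophage and monocyte genes rose in 13 of 19 (15 adjusted over the list alone), with Lyz2 at 2.27 ± 0.25. The median was 1.61 (adjusted p = 1.65e-05, and adjusted p = 0.292 with an estimated correlation). B cell genes had 9 of 20 members up and 1 down (12 and 1 adjusted over the list alone), among them the surface receptor gene Cd22 (2.67 ± 0.49). The median was 1.85 (adjusted p = 0.0227, and adjusted p = 0.674 with an estimated correlation). Their mean level lay at 4.61 and 5.18 log2 CPM in T58A lymphomas 1 and 2 and at 1.86 in T58A lymphoma 3, against 2.85 ± 0.09 in controls. The call was lost without T58A lymphoma 1 (1.77, adjusted p = 0.0784) or 2 (1.33, adjusted p = 0.267) and turned to −0.95 without both (adjusted p = 0.00996), a check added after the values were seen.

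In edgeR's quasi-likelihood test 5646 of 15606 genes (36.2%) differed between T58A lymphomas and controls, 2938 up and 2708 down, a balance that turned with library size only (2802 up and 2834 down). In 60% of genes the libraries of both groups did not overlap, where chance gives 10%. With the libraries of title code H only, control 3 was the lone control left, and fewer genes passed. Camera called 5 of the 36 lists up and 9 down, and with an estimated correlation it called 0, with 8 lists at an unadjusted p under 0.05, against 15 by fry.

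S62A lymphomas were compared with the same controls. All S62A libraries, splenomegaly included, carry the title code I and no control does, so code and group cannot be told apart against controls. Thymic epithelium genes were lower in every member measured, genes of antigen presentation and interferon response were lower, and genes of ribosome assembly were higher. Ccl25 fell to 5.54 ± 1.77 CPM (−6.91 ± 0.3, adjusted p = 3.39e-07) and Prss16 from 1100 ± 16.8 to 1.44 ± 1.41 CPM (−9.56 ± 0.67, adjusted p = 4.32e-06). Tfrc, the transferrin receptor for iron uptake, rose from 160 ± 15.8 to 1680 ± 779 CPM (3.39 ± 0.38, adjusted p = 6.68e-05). S100a8, an abundant protein of neutrophils, fell from 45.5 ± 13.3 to 1.32 ± 0.944 CPM (−5.09 ± 0.7, adjusted p = 0.000252).

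The largest rises again included Esx1 (9.93 ± 1.22), Prox1 (9.45 ± 0.72), Tbx4 (9.41 ± 0.83), Notum (8.45 ± 0.63) and Sp5 (7.89 ± 0.67). Barx1, a homeobox factor of stomach and jaw, rose from 0.915 ± 0.0853 to 291 ± 187 CPM (8.31 ± 0.75), and Fcgr4, an immunoglobulin receptor of myeloid cells, from 0.597 ± 0.0553 to 240 ± 217 CPM (8.64 ± 1.62, adjusted p = 0.00161). Among the largest falls, Dnajc6, a cochaperone of clathrin uncoating, had 3 reads in all S62A lymphomas against 76.9 ± 1.34 CPM in controls, a ratio of 1150 with a 95% counting interval of 392 to 5560. Ptcra fell by 9.21 ± 0.49.

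Ribosome biogenesis had 27 of 29 members up (27 adjusted over the list alone), with Rrs1 at 1.42 ± 0.11. The median was 1.38 (adjusted p = 2.3e-19, and adjusted p = 0.131 with an estimated correlation). Nucleotide synthesis had 13 of 22 up and 3 down (13 and 4 adjusted over the list alone), and glycolysis and lactate 10 of 19 up and 2 down (10 and 2 adjusted over the list alone). Atic, an enzyme of purine synthesis, rose by 1.53 ± 0.12 and the glycolytic gene Tpi1 by 1.93 ± 0.15. The medians were 0.7 and 0.76 (adjusted p = 0.00384 and 0.00627, and adjusted p = 0.438 and 0.543 with an estimated correlation). Amino acid and one-carbon metabolism had 13 of 19 up and 1 down (13 and 1 adjusted over the list alone), a median of 0.94 and an adjusted p of 2.22e-05, with adjusted p = 0.244 with an estimated correlation. DNA damage repair had 12 of 26 up and 1 down (12 and 1 adjusted over the list alone), among them Parp1 (1.08 ± 0.17). The median was 0.44 (adjusted p = 0.014, and adjusted p = 0.511 with an estimated correlation). TGF-beta and extracellular matrix had 9 of 20 up and 2 down (9 and 2 adjusted over the list alone), with Thbs1 at 2.73 ± 0.45. The median was 1.49 (adjusted p = 0.0389, and adjusted p = 0.662 with an estimated correlation). That call was lost without S62A lymphoma 2 (1.3, adjusted p = 0.0637) or 3 (1.18, adjusted p = 0.169).

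Interferon response genes fell in 19 of 26 members (19 adjusted over the list alone), with Mx2, an antiviral GTPase gene, at −3.7 ± 0.39. The median was −2.08 (adjusted p = 3.32e-06, and adjusted p = 0.518 with an estimated correlation). Antigen presentation genes fell in 16 of 18 and rose in 1 (17 and 1 adjusted over the list alone), with Tap2 at −2.76 ± 0.18 and Psmb9 at −2.67 ± 0.24. The median was −1.75 (adjusted p = 2.76e-07, and adjusted p = 0.467 with an estimated correlation). Notch target genes had 10 of 16 down and 1 up (10 and 1 adjusted over the list alone), the riser being Gata3 (1.24 ± 0.28), with Notch1 at −4.95 ± 0.25. The median was −2.14 (adjusted p = 8.18e-07, and adjusted p = 0.235 with an estimated correlation).

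Pan T cell genes fell in 12 of 17 members (12 adjusted over the list alone) and double-positive thymocyte genes in 14 of 20, with 1 up (15 and 1 adjusted over the list alone). The medians were −1.93 and −1.61 (adjusted p = 1.38e-05 and 1.07e-06, and adjusted p = 0.361 and 0.175 with an estimated correlation). Mature T cell genes fell in 8 of 18 (8 adjusted over the list alone) and immature B cell genes in 8 of 12, with 1 up (8 and 1 adjusted over the list alone). The medians were −1.7 and −1.73 (adjusted p = 0.000154 and 0.0039, and adjusted p = 0.438 and 0.25 with an estimated correlation). Granulocyte genes fell in 14 of 18 (14 adjusted over the list alone). The median was −5.15, or −4.66 with the 4 members at 0 reads set at their bounds (adjusted p = 0.000222, and adjusted p = 0.467 with an estimated correlation). Ly6g, a surface protein of mouse neutrophils with near-identical relatives, had no reads and was at least 24.3-fold lower. Thymic epithelium genes fell in all 20 (20 adjusted over the list alone). The median was −4.83 (adjusted p = 2.11e-19, and adjusted p = 0.125 with an estimated correlation). Macrophage and monocyte genes rose in 10 of 19 (12 adjusted over the list alone), with Itgam at 6.31 ± 0.55. The median was 1.07 (adjusted p = 0.0025, and adjusted p = 0.438 with an estimated correlation).

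The quasi-likelihood test of edgeR called 6885 genes between S62A lymphomas and controls, 3414 up and 3471 down (2857 and 3919 with library size only), and 60.3% of genes did not overlap against 10% by chance. Camera called 7 lists up and 9 down, and 0 with an estimated correlation, with 6 at an unadjusted p under 0.05, against 22 by fry.

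Genes that differed from control in both lymphoma groups were counted next. Over all 12 libraries 2258 genes rose in both and 2119 fell in both, where independent lists of these sizes would share 643 and 602. Called in opposite directions were 8 genes. With these groups' 9 libraries alone 4 were, and 2268 and 1984 were shared, 635 and 544 for independent lists. In 20 simulations of unchanged groups with shared controls at most 0 were shared, which decides nothing, as such groups give few calls. The covariance of the log2 fold changes was 2.53 against a mean of 0.118 in the simulations, and their correlation across genes 0.84 against 0.49. Genes are not independent replicates, and with 3 controls no split left 2 in each part, so some of the excess may come from the shared controls.

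S62A and T58A lymphomas were then compared directly. Their labels differ in the mutant and also in a letter code of the titles, H in all T58A and I in all S62A lymphomas, so the mutant and the code cannot be told apart by design. Genes of neutrophils and of B cells stood lower in S62A lymphomas, and few genes stood higher. S100a8 was lower (log2 difference −5.23 ± 0.71, adjusted p = 0.0165), at 1.32 ± 0.944 CPM against 50.1 ± 25, and Ngp, a neutrophil granule protein, at 0.178 ± 0.308 against 26.1 ± 14.3 CPM (−7.13 ± 1.21, adjusted p = 0.0199), with all its reads there in S62A lymphoma 3. Pax5, the factor of B cell identity, had 3 reads in all S62A lymphomas against 4.27 ± 3.07 CPM, a ratio of 64.5 with a 95% counting interval of 21.8 to 315 (adjusted p = 0.0193). Its log2 difference was −5.83 ± 0.99, and the 3 reads lay in S62A lymphoma 2. Fzd10, a Wnt receptor, was at 0.204 ± 0.135 against 73.4 ± 57.8 CPM (−8.45 ± 1.06, adjusted p = 0.0106), and Krt5, a keratin of medullary thymic epithelium, at 11 ± 6.74 against 83 ± 28 CPM (−2.92 ± 0.44, adjusted p = 0.0171).

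Higher in S62A lymphomas were Limch1, which binds actomyosin, at 84.6 ± 58.5 against 8.68 ± 3.01 CPM (3.28 ± 0.46, adjusted p = 0.0165), Bcar3 at 3.05 ± 0.37 (adjusted p = 0.00956), Eif5a2, a translation factor, at 2.02 ± 0.38 (adjusted p = 0.0269) and Glo1, which detoxifies methylglyoxal, at 1.64 ± 0.19 (adjusted p = 0.00829). The largest difference upward was that of Rfx4, a ciliary transcription factor gene, at 41.2 ± 58.8 against 0.164 ± 0.16 CPM (7.88 ± 1.66, adjusted p = 0.0319). It did not pass without T58A lymphoma 1 (7.33, adjusted p = 0.055), 2 (8.76, 0.0985) or 3 (7.91, 0.0638) or S62A lymphoma 3 (5.42, 0.0622). Other genes lower in S62A lymphomas were Clu (−3.2 ± 0.35), the TGF-beta binding protein gene Ltbp1 (−3.16 ± 0.52), Mef2c (−2.27 ± 0.37), Lmo2 (−1.41 ± 0.26) and Mx2 (−2.51 ± 0.38).

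Granulocyte genes were lower in 9 of 18 members (15 adjusted over the list alone). The median was −5.22, or −4.7 with 4 members at their bounds (adjusted p = 3.45e-14, and adjusted p = 0.175 with an estimated correlation). B cell genes were lower in 9 of 20 (17 lower and 1 higher adjusted over the list alone). The median was −3.11 (adjusted p = 7.04e-11, and adjusted p = 0.361 with an estimated correlation). Interferon response genes were lower in 2 of 26 and antigen presentation genes in 2 of 18 (11 and 15 adjusted over the list alone). The medians were −1.34 and −1.03 (adjusted p = 6.81e-07 and 2.8e-08, and adjusted p = 0.504 and 0.438 with an estimated correlation). The B cell, interferon and antigen presentation calls were lost without T58A lymphomas 1 and 2 together, where the medians were −0.34 for B cell genes (adjusted p = 0.485), −0.12 for interferon response (adjusted p = 0.604) and 0.01 for antigen presentation (adjusted p = 0.887). Thymic epithelium genes were lower in 6 of 20 (12 lower and 1 higher adjusted over the list alone). The median was −1.84 (adjusted p = 1.63e-06, and adjusted p = 0.25 with an estimated correlation). Early double-negative thymocyte genes were lower in 3 of 17 (7 lower and 1 higher adjusted over the list alone). The median was −1.1 (adjusted p = 4.08e-05, and adjusted p = 0.21 with an estimated correlation), and endothelium genes in 1 of 17 (3 adjusted over the list alone). The median was −0.59 (adjusted p = 0.000475, and adjusted p = 0.461 with an estimated correlation).

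DNA replication had no member past the threshold of edgeR over all genes, and 6 were higher adjusted over the list alone. The median was 0.26 (adjusted p = 1.49e-05, and adjusted p = 0.541 with an estimated correlation). DNA damage repair had a median of 0.34 (adjusted p = 0.000123, and adjusted p = 0.318 with an estimated correlation) and regulators of MYC stability 0.27 (adjusted p = 0.00355, and adjusted p = 0.442 with an estimated correlation), and neither had a member past the threshold over all genes or adjusted over the list alone. A further 11 lists were called with medians that lost the call without at least 1 library. Higher were ribosome biogenesis at 0.15 (adjusted p = 0.00699), lost without T58A 2 (0.11, adjusted p = 0.092), nucleotide synthesis at 0.22 (adjusted p = 0.0232), lost without T58A 2 (0.16), S62A 2 (0.23) or S62A 3 (0.14), glycolysis at 0.2 (adjusted p = 0.0119), lost without S62A 1 (0.17, adjusted p = 0.102) or 2 (0.17, adjusted p = 0.097), and mitosis at 0.23 (adjusted p = 0.00383), lost without S62A 2 (0.13) or 3 (0.2). Lower were mature T cell genes at −0.49 (adjusted p = 0.0209), lost without T58A 1 (−0.57), T58A 2 (−0.19) or S62A 3 (−0.49), plasma cell and germinal centre genes at −0.96 (adjusted p = 0.00366), lost without T58A 2 (−0.43) or S62A 1 (−0.7), and dendritic cell genes at −0.65 (adjusted p = 0.0369), lost without T58A 1 (−0.54), T58A 2 (−0.45), S62A 1 (−0.76) or S62A 2 (−0.74). Fibroblast genes at −0.69 (adjusted p = 0.00278) lost the call without T58A 3 (−0.31), adipocyte genes at −2.34 (adjusted p = 0.00547) without T58A 1 (−1.49), erythroid genes at −1.62 (adjusted p = 0.0175) without T58A 3 (−0.78) or S62A 3 (−1.45), and megakaryocyte and platelet genes at −0.97 (adjusted p = 0.0171) without T58A 3 (−0.54) or S62A 1 (−0.85). With an estimated correlation the adjusted p of these 11 lists lay between 0.361 and 0.654.

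By edgeR's quasi-likelihood test 492 genes differed between the lymphoma groups, 134 higher and 358 lower in S62A lymphomas, and 21.1% of genes did not overlap against 10% by chance. The count rose to 783 without T58A lymphoma 1 and fell to 139 without T58A lymphoma 2 and to 267 without S62A lymphoma 2, was 319 without T58A lymphomas 1 and 2, and of 46 named genes 30 lost the call without some library and 45 in at least 1 alternative. A fit to these 6 libraries alone called 0, with 2045 genes at an unadjusted p under 0.05, against 4 by limma voom and 1754 by DESeq2. Camera called 7 lists higher and 14 lower, and 0 with an estimated correlation, with 3 at an unadjusted p under 0.05, against 8 by fry.

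Thymic masses of S62A animals with splenomegaly were compared with control tissue. Genes of plasma cells, B cells, antigen presentation, macrophages and vessels stood higher, and most genes of double-positive thymocytes and of thymic epithelium stood lower. Rag1, a subunit of the recombinase of lymphocyte receptors (chromosome 2 from 101478411 to 101489689), fell from 2240 ± 167 to 0.903 ± 0.36 CPM (−11.28 ± 0.53, adjusted p = 3.57e-07). Jchain, which joins secreted IgM and IgA (chromosome 5 from 88948834 to 88956922), rose from 73.6 ± 8.57 to 16500 ± 3570 CPM (7.81 ± 1.1, adjusted p = 0.000199) and was the most abundant gene of all 3 masses. Cxcl13, the chemokine of B cell follicles, rose from 2.62 ± 0.514 to 681 ± 311 CPM (8.02 ± 0.68, adjusted p = 7.44e-06), and Glycam1, a mucin of high endothelial venules, from 0.218 ± 0.0522 to 74.2 ± 33.1 CPM (8.38 ± 1.18, adjusted p = 0.000193).

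Further large rises were those of Slpi, a secreted protease inhibitor, from 6.16 ± 2.49 to 10300 ± 7870 CPM (10.71 ± 1.76), and Fcgr4 (10.01 ± 1.69), at 1450, 291 and 133 CPM in masses 1, 2 and 3 and at 8.5 without the first. Among the largest falls, Dntt, the polymerase that adds bases at receptor junctions, fell by 10.42 ± 1.24, and Rag2 was at −11.09 ± 0.91. Krt5 fell by 10.38 ± 0.73, and Slc5a9, a sugar transporter gene, had no reads and was at least 1750-fold lower. Pax1, a factor of thymic epithelium, had 3 reads in all masses against 153 ± 18.3 CPM, a ratio of 2160 with a 95% counting interval of 738 to 10500.

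B cell genes rose in 19 of 20 members (19 adjusted over the list alone), with Cd22 at 6.13 ± 0.56 and Ebf1 at 3.77 ± 0.41. The median was 4.65 (adjusted p = 1.03e-09, and adjusted p = 0.361 with an estimated correlation). Plasma cell and germinal centre genes rose in 14 of 16 and fell in 1, Bcl6 (14 and 1 adjusted over the list alone), with Prdm1, the master factor of plasma cells, at 5.54 ± 0.34. The median was 4.34 (adjusted p = 1.37e-10, and adjusted p = 0.244 with an estimated correlation). Macrophage and monocyte genes rose in 17 of 19 (18 adjusted over the list alone), with Csf1r at 3.62 ± 0.36, and dendritic cell genes in 10 of 16, with 3 down (11 and 3 adjusted over the list alone), with Irf8 at 2.63 ± 0.34. Their medians were 2.89 and 1.64 (adjusted p = 2.76e-09 and 0.0247, and adjusted p = 0.175 and 0.543 with an estimated correlation). Endothelium genes rose in all 17 (17 adjusted over the list alone), with Plvap at 3.18 ± 0.22, and fibroblast genes in 7 of 17 (7 adjusted over the list alone), with Pdgfra at 3.38 ± 0.27. Their medians were 2.28 and 0.86 (adjusted p = 1.29e-08 and 0.0298, and adjusted p = 0.25 and 0.646 with an estimated correlation), and the fibroblast call was lost without splenomegaly 1 (0.79, adjusted p = 0.104).

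Pan T cell genes fell in 16 of 17 members (16 adjusted over the list alone), with the receptor gene Cd27 at −3.95 ± 0.13 and Lck at −3.94 ± 0.16, and double-positive thymocyte genes in 19 of 20 (19 adjusted over the list alone), with Cd8b1 at −6.42 ± 0.37. The medians were −3.27 and −6.39 (adjusted p = 1.08e-19 and 4.55e-20, and adjusted p = 0.131 and 0.0644 with an estimated correlation). Thymic epithelium genes fell in 17 of 20 (17 adjusted over the list alone). The median was −7.96 (adjusted p = 2.6e-16, and adjusted p = 0.131 with an estimated correlation). Early double-negative thymocyte genes rose in 10 of 17 and fell in 3 (10 and 3 adjusted over the list alone). The median was 1.65 (adjusted p = 0.00333, and adjusted p = 0.297 with an estimated correlation). The risers include Mef2c (5.33 ± 0.41) and Lmo2 (4.05 ± 0.29), which B cells and endothelium also express, while Notch1 fell by 1.94 ± 0.22 and Gata3 by 2.1 ± 0.29.

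Antigen presentation genes rose in 16 of 18 members (16 adjusted over the list alone), with Ctss at 4.15 ± 0.35. The median was 2.28 (adjusted p = 2.79e-07, and adjusted p = 0.461 with an estimated correlation). Interferon response genes rose in 11 of 26 and fell in 1 (11 and 1 adjusted over the list alone), and immune checkpoint and cytotoxic genes rose in 11 of 19 and fell in 2 (12 and 2 adjusted over the list alone). Cxcl9, a chemokine induced by interferon gamma, rose by 5.16 ± 0.56, and Havcr2, the checkpoint receptor TIM-3, by 2.55 ± 0.39. The medians were 0.81 and 1.84 (adjusted p = 0.00293 and 0.00627, and adjusted p = 0.646 and 0.511 with an estimated correlation). TGF-beta and extracellular matrix rose in 12 of 20 (12 adjusted over the list alone), with Tgfbi at 4.04 ± 0.56. The median was 1.22 (adjusted p = 0.00547, and adjusted p = 0.574 with an estimated correlation). Ribosome biogenesis had 15 of 29 up and 3 down (16 and 3 adjusted over the list alone) and amino acid metabolism 10 of 19 up and 1 down (10 and 1 adjusted over the list alone). The medians were 0.38 and 0.56 (adjusted p = 0.0199 and 0.00366, and adjusted p = 0.639 and 0.42 with an estimated correlation).

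Mitosis genes fell in 22 of 25 members (23 adjusted over the list alone), with Cenpf at −1.84 ± 0.21, and DNA replication genes in 19 of 25 (20 adjusted over the list alone), with the helicase gene Mcm7 at −1.17 ± 0.11. The medians were −1 and −0.64 (adjusted p = 8.3e-07 and 0.00205, and adjusted p = 0.511 and 0.646 with an estimated correlation). DNA damage repair fell in 12 of 26 and rose in 1 (13 and 1 adjusted over the list alone), with Xrcc6 at −3.04 ± 0.32. The median was −0.45 (adjusted p = 0.0383, and adjusted p = 0.544 with an estimated correlation). That call was lost without splenomegaly 1 (−0.34, adjusted p = 0.0932) or T58A lymphoma 2, which enters the shared spread (−0.41, adjusted p = 0.0513). Notch target genes fell in 10 of 16 and rose in 1 (10 and 1 adjusted over the list alone), with the T cell factors Tcf7 at −4.75 ± 0.2 and Bcl11b at −4.31 ± 0.2. The median was −1.76 (adjusted p = 6.02e-07, and adjusted p = 0.22 with an estimated correlation).

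In all, 7681 genes differed between splenomegaly masses and controls by edgeR's quasi-likelihood test, 3578 up and 4103 down, and 70.5% of genes did not overlap against 10% by chance. The median log2 fold change of all genes was −0.084 and became −0.191 with library size only. Camera called 13 lists up and 7 down, and 0 with an estimated correlation, with 7 at an unadjusted p under 0.05, against 26 by fry.

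**Figure D2:**
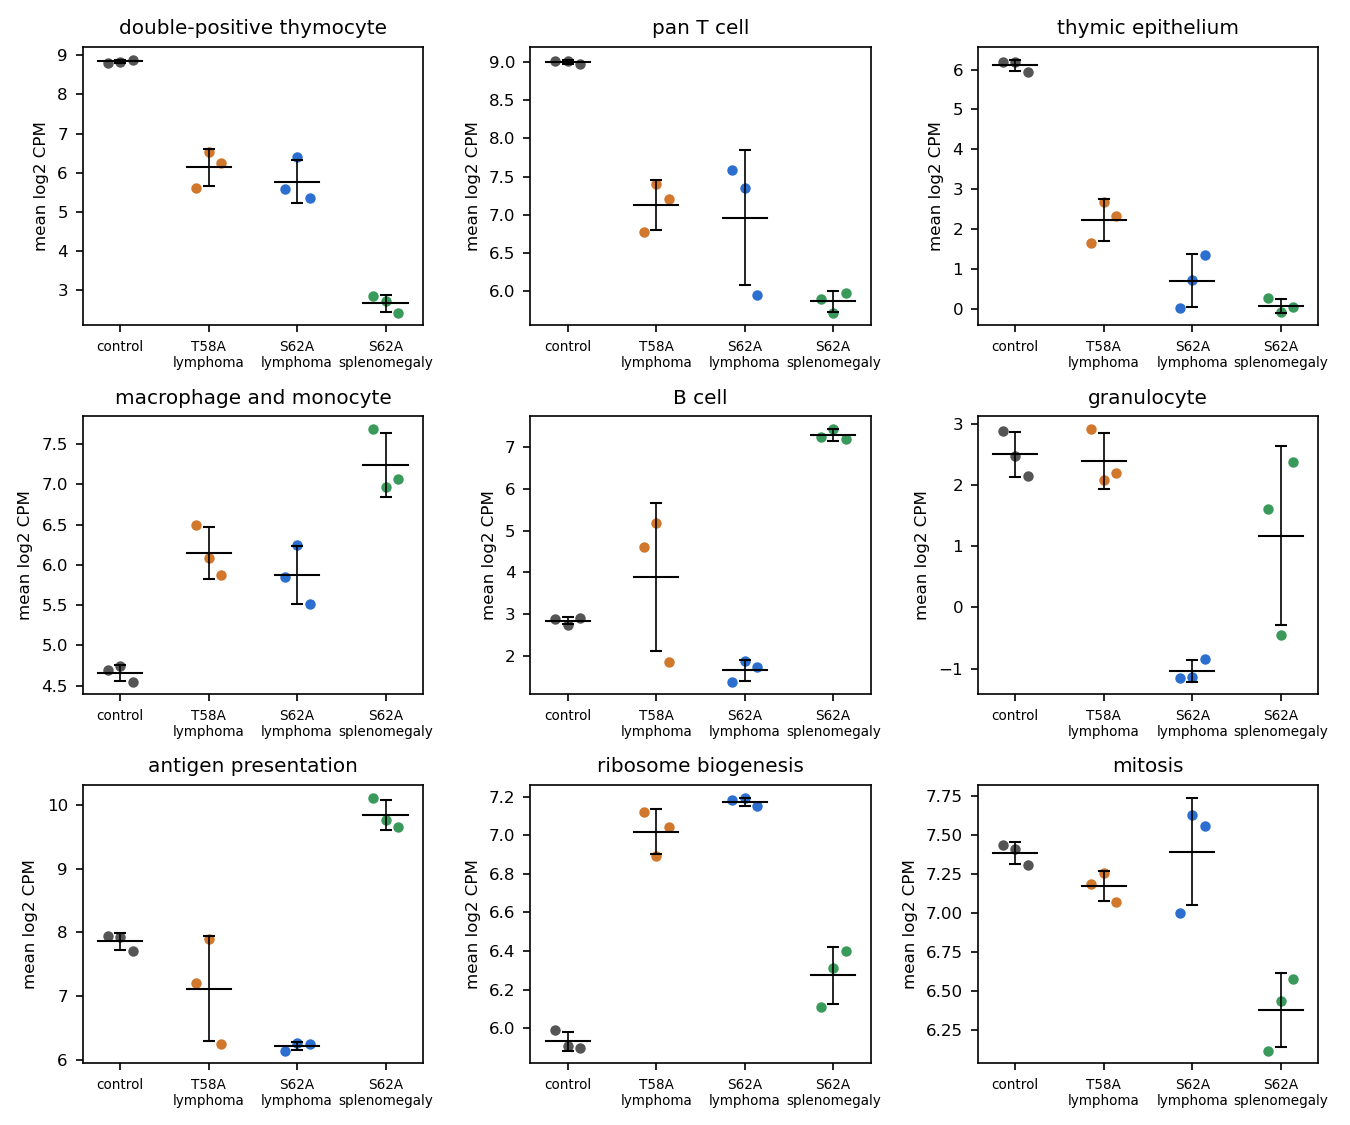
Mean log2 CPM of the members of 9 gene lists in each of the 12 libraries (points), with the mean and SD of each group of 3. B cell genes lie between 7.2 and 7.45 in splenomegaly masses and between 1.86 and 5.18 in T58A lymphomas, and thymic epithelium genes lie at 5.94 or higher in controls only.

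Splenomegaly masses and S62A lymphomas carry the same mutant, and their labels differ in cell types and in endogenous MYC. Genes of antigen presentation and interferon response, B cells and plasma cells stood higher in the splenomegaly masses, and genes of double-positive thymocytes, ribosome assembly and cell division stood lower. Mzb1, a chaperone of immunoglobulin assembly, was at 2140 ± 728 against 13.5 ± 11.3 CPM (7.31 ± 1.32, adjusted p = 0.000823). Psmb9, a subunit of the immunoproteasome, was at 314 ± 25 against 20.8 ± 1.13 CPM (3.91 ± 0.26, adjusted p = 2.18e-06). Tcf7 was lower, at 153 ± 33.4 against 5210 ± 504 CPM (−5.09 ± 0.21, adjusted p = 2.01e-07), as was Rag1, at 0.903 ± 0.36 against 875 ± 420 CPM (−9.93 ± 0.51, adjusted p = 4.34e-07). Ccnb1, the mitotic cyclin, was also lower (−2.81 ± 0.14, adjusted p = 3.79e-07).

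Glycam1 had 2 reads in S62A lymphomas against 74.2 ± 33.1 CPM in the masses, a ratio of 1810 with a 95% counting interval of 501 to 15000, and Cacna1h, a calcium channel subunit, was higher by 7.31 ± 0.85. Sim2, a neural transcription factor gene, Mixl1, a factor of early mesoderm, and Kcnn2, a potassium channel gene, had no reads in the masses and were at least 4780-fold, 1170-fold and 629-fold lower there. Barx1 and the Wnt inhibitor gene Wif1 had 1 read each, with ratios of 12500 (2250 to 495000) and 8100 (1450 to 320000).

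Antigen presentation genes were higher in all 18 members and interferon response genes in 25 of 26 (18 and 25 adjusted over the list alone), with the GTPase gene Igtp at 3.44 ± 0.3. The medians were 3.82 and 3.45 (adjusted p = 8.14e-19 and 1.67e-11, and adjusted p = 0.25 and 0.361 with an estimated correlation). B cell genes were higher in 19 of 20 and plasma cell and germinal centre genes in all 16 (19 and 16 adjusted over the list alone). The medians were 5.94 and 3.94 (adjusted p = 1.04e-10 and 5.66e-10, and adjusted p = 0.361 and 0.25 with an estimated correlation). Immune checkpoint and cytotoxic genes were higher in 12 of 19 and lower in 1 (12 and 1 adjusted over the list alone), and dendritic cell genes higher in 11 of 16 and lower in 1, Ccr9 (12 and 1 adjusted over the list alone). The medians were 2.88 and 2.01 (adjusted p = 0.000123 and 0.000324, and adjusted p = 0.361 for each with an estimated correlation). Macrophage and monocyte genes were higher in 13 of 19 and lower in 1, Itgam at −3.58 ± 0.48 (13 and 1 adjusted over the list alone). The median was 1.48 (adjusted p = 0.00283, and adjusted p = 0.438 with an estimated correlation). Endothelium genes were higher in all 17 (17 adjusted over the list alone), with Plvap at 3.42 ± 0.22. The median was 2.21 (adjusted p = 8.41e-08, and adjusted p = 0.293 with an estimated correlation). Megakaryocyte and platelet genes were higher in 5 of 8 and lower in 1 (5 and 1 adjusted over the list alone). The median was 1.77 (adjusted p = 0.015, and adjusted p = 0.361 with an estimated correlation); Vwf (3.59 ± 0.4) is also a gene of endothelium. Granulocyte genes were higher in 13 of 18 and lower in 2 (14 and 2 adjusted over the list alone). The median was 3.76, or 3.25 with 4 members at their bounds (adjusted p = 0.0227, and adjusted p = 0.639 with an estimated correlation). That call was lost without splenomegaly 3 (2.85, adjusted p = 0.0719).

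Early double-negative thymocyte genes were higher in 15 of 17 and lower in 2 (15 and 2 adjusted over the list alone), and mature T cell genes higher in 13 of 18 and lower in 3 (13 and 3 adjusted over the list alone). S1pr1, the receptor for leaving lymphoid organs, was higher by 3.51 ± 0.29. The medians were 2.77 and 2.79 (adjusted p = 2.64e-06 and 0.00173, and adjusted p = 0.175 and 0.518 with an estimated correlation). Pan T cell genes were lower in 8 of 17 and higher in 1 (8 and 1 adjusted over the list alone), and double-positive thymocyte genes lower in 15 of 20 (16 adjusted over the list alone). The medians were −1.13 and −3.07 (adjusted p = 3.05e-07 and 3.56e-08, and adjusted p = 0.318 and 0.131 with an estimated correlation).

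Ribosome biogenesis was lower in 26 of 29 members (26 adjusted over the list alone), with Nle1 at −1.6 ± 0.14, and nucleotide synthesis lower in 16 of 22 and higher in 1 (17 and 1 adjusted over the list alone). The medians were −0.93 and −0.7 (adjusted p = 7.64e-08 and 0.00187, and adjusted p = 0.297 and 0.404 with an estimated correlation). DNA replication was lower in 22 of 25, mitosis in 20 of 25 and DNA damage repair in 19 of 26 (23, 21 and 20 adjusted over the list alone). Their medians were −0.81, −0.83 and −0.77 (adjusted p = 4.28e-05, 8.3e-07 and 2.39e-05, and adjusted p = 0.544, 0.511 and 0.263 with an estimated correlation). Regulators of MYC stability were lower in 9 of 15 and higher in 1, Fbxw7, a ubiquitin ligase subunit for MYC, at 0.96 ± 0.21 (10 and 1 adjusted over the list alone). Their median was −0.44 (adjusted p = 0.0298, and adjusted p = 0.544 with an estimated correlation), a call lost without S62A lymphoma 3 (−0.48, adjusted p = 0.0668) or splenomegaly 1 (−0.34, adjusted p = 0.0867). By edgeR's quasi-likelihood test 8472 genes differed, 4002 higher and 4470 lower in the masses (4267 and 4019 with size factors of the DESeq2 kind), and 58.1% did not overlap against 10% by chance. Camera called 12 lists up and 8 down, and 0 with an estimated correlation, with 6 at an unadjusted p under 0.05, against 26 by fry.

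**Figure D3:**
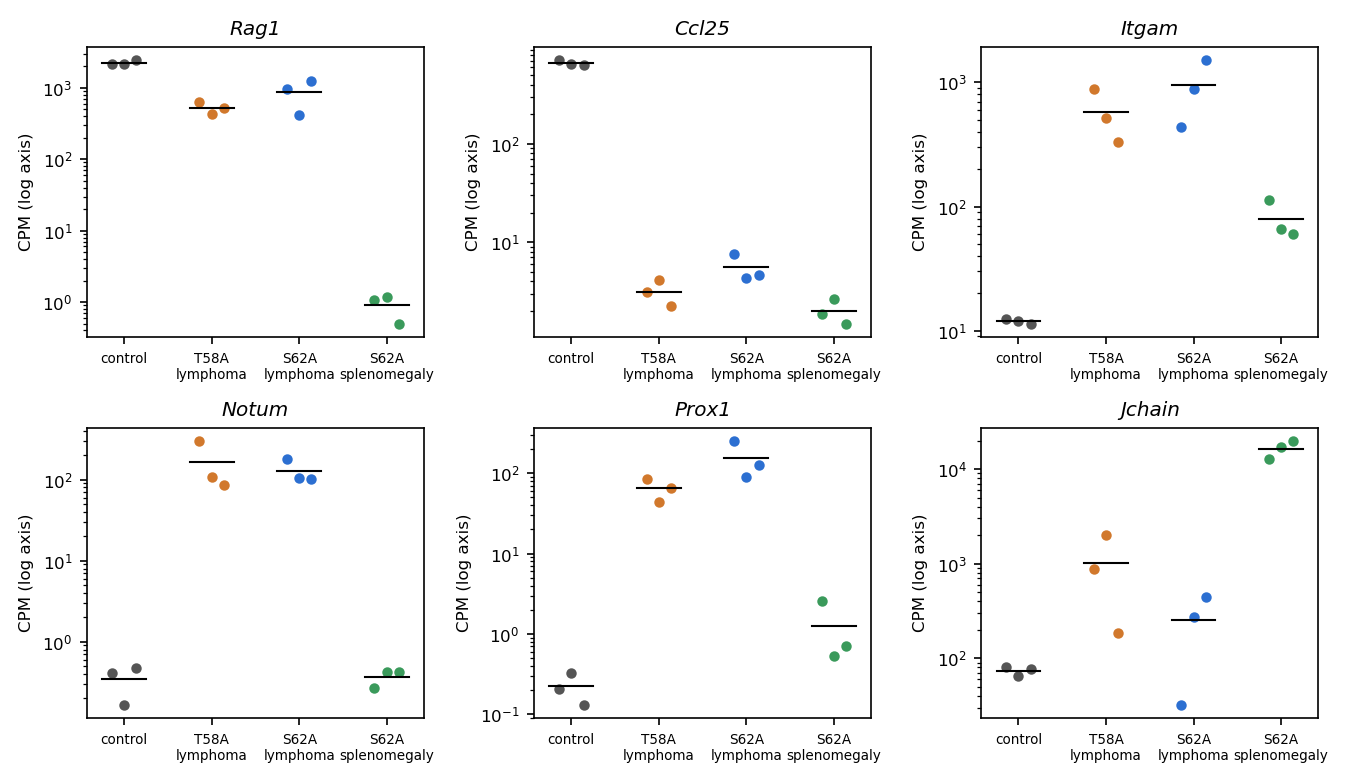
CPM on a log axis of Rag1, Ccl25, Itgam, Notum, Prox1 and Jchain in each of the 12 libraries (points), with the mean of each group of 3. Jchain averages 16500 CPM in splenomegaly masses against 73.6 in controls, and Notum averages 163 and 128 CPM in T58A and S62A lymphomas against 0.352 in controls.

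Lists without a camera call in any comparison held single members that differed from control. Cdkn1a, the p53 target that blocks the cell cycle, rose by 3.66 ± 0.41 in T58A and 3.19 ± 0.4 in S62A lymphomas (adjusted p = 9.37e-05 and 0.000139), and Cdkn2a, the locus of p16 and ARF, by 3.62 ± 0.61, 3.92 ± 0.62 and 3.71 ± 0.61 in T58A lymphomas, S62A lymphomas and splenomegaly masses (adjusted p = 0.00108, 0.000551 and 0.000554). Bmf, a gene that promotes cell death, fell by 2.8 ± 0.28, 3.54 ± 0.29 and 1.87 ± 0.27 in T58A lymphomas, S62A lymphomas and splenomegaly masses. In T58A lymphomas p53 target genes had 5 of 22 up and 4 down, the BCL2 family 3 of 17 up and 3 down, and ARF and CDK inhibitor genes 6 of 18 up and 6 down (5 and 4, 3 and 3, 6 and 7 adjusted over the list alone). The medians were 0.23, 0.3 and −0.25 (adjusted p = 0.51, 0.931 and 0.931). In S62A lymphomas the medians of these 3 lists were 0.14, 0.1 and 0.05 (adjusted p = 0.378, 0.78 and 0.671), and in splenomegaly masses −0.12, 0.61 and −0.54 (adjusted p = 0.864, 0.165 and 0.25). Natural killer cell genes had medians of 0.29, 1.83 and 2.4 against control in the same order (adjusted p = 0.976, 0.695 and 0.0691) and skeletal muscle genes −0.84, −0.72 and 1.28 (adjusted p = 0.484, 0.272 and 0.516). MYC family and partners had 1 of 14 up and 6 down, 2 up and 5 down, and 3 up and 6 down (1 and 6, 2 and 6, 3 and 6 adjusted over the list alone). The medians were −0.49, −0.36 and −0.32 (adjusted p = 0.0517, 0.189 and 0.191).

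Some lists without a call gained it with size factors of the DESeq2 kind, as MYC family in T58A lymphomas and immature B cell genes in splenomegaly masses against control (0.0483 each). With library size only, MYC family, natural killer cell genes in the same masses and fibroblast genes in masses against S62A lymphomas did (0.0467, 0.0456 and 0.0495). Others gained it when 1 library was left out. Against T58A lymphomas and controls these were MYC family and partners without control 1, 2 or 3 or S62A 1 (adjusted p = 0.0396, 0.0406, 0.0432 and 0.0441), nucleotide synthesis (main adjusted p = 0.051) without control 1 or 2, T58A 2 or any splenomegaly mass (0.0406, 0.0492, 0.0215, 0.0487, 0.0441 and 0.0361), glycolysis without control 3 (0.0299), plasma cell genes without T58A 3 (0.00177), fibroblast genes without T58A 1 or S62A 1 or 3 (0.0418, 0.0441 and 0.0412), endothelium without control 3 or T58A 1 (0.00443 and 0.0314) and adipocyte genes without control 1 (0.0429). In S62A lymphomas against control they were DNA replication without S62A 1 (0.0178), early double-negative genes without control 3 (0.0343), B cell genes without T58A 3 (0.00831), dendritic cell genes without T58A 2 or 3 (0.0317 and 0.0346) and adipocyte genes without control 1 or 2 (0.00192 and 0.00821). In splenomegaly masses against control they were glycolysis without control 3 or splenomegaly 2 (0.0218 and 0.0177), immature B cell genes without any control, T58A 1, S62A 2 or splenomegaly 3 (0.0368, 0.0309, 0.0288, 0.0183, 0.0145 and 0.049) and natural killer cell genes without S62A 1 or 3 or splenomegaly 3 (0.017, 0.0412 and 0.0477).

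Between the lymphoma groups, amino acid metabolism gained a call without S62A 1 (0.0157), Notch targets without T58A 1 or 3, S62A 3 or splenomegaly 3 (0.00499, 0.0455, 0.0178 and 0.049), and immune checkpoint genes without T58A 3 or S62A 1 (0.0125 and 0.00706). TGF-beta and extracellular matrix gained it without T58A 1 or 2 or S62A 2 or 3 (0.0143, 0.0135, 0.0337 and 0.000244), immediate early genes without S62A 3 (0.027) and double-positive genes without S62A 2 (0.048). Immature B cell genes gained it without T58A 3 (0.0441), macrophage genes without T58A 3 or S62A 2 (0.0311 and 0.0378), and natural killer cell genes without T58A 2 or S62A 3 (0.0293 and 0.0367). Pan T cell genes turned from a test downward to a call upward without S62A 3 (median 0.24, adjusted p = 0.0191). Between splenomegaly masses and S62A lymphomas, the BCL2 family gained a call without S62A 2 (0.0154), natural killer cell genes without S62A 1 (0.0143), and fibroblast genes without control 1, 2 or 3, S62A 3 or splenomegaly 2 or 3 (0.0439, 0.0448, 0.0402, 0.0016, 0.0491 and 0.0308). Adipocyte genes gained it without control 1, 2 or 3 or splenomegaly 3 (0.0274, 0.0431, 0.00487 and 0.0424), and erythroid genes without control 1 or 3, S62A 2 or splenomegaly 2 or 3 (0.0494, 0.0338, 0.0449, 0.00992 and 0.0301).

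Median, mean and test differed in sign only in lists without a call. In T58A lymphomas against control these were the BCL2 family, ARF and CDK inhibitor, immune checkpoint, early double-negative, natural killer cell and megakaryocyte genes, and in S62A lymphomas mitosis, the BCL2 family, plasma cell and endothelium genes. In splenomegaly masses against control they were p53 target, mature T cell and immature B cell genes. Between the lymphoma groups they were MYC family, p53 target, pan T cell and double-positive genes, and between splenomegaly masses and S62A lymphomas MYC family, p53 target, Notch target and immature B cell genes.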

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

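The tests of a lower share of thymocytes alone, of plasma cell beside B cell RNA, and of granulocyte RNA from splenomegaly libraries were chosen only after the result was seen, and the list of lymph node genes was drawn up after the data were examined.

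Effects against control had opposite signs in T58A and S62A lymphomas, with at least 1 of them past the threshold, in 184 of the 492 genes that differed between these groups by edgeR's quasi-likelihood test. In 8 genes both effects passed. Among the genes named by the fixed rule 19 met this condition, and those reported are given here as the log2 difference of S62A from T58A lymphomas. Fzd10 stood above control in T58A lymphomas (2.27, adjusted p = 0.0297) and below it in S62A lymphomas (−6.18, adjusted p = 0.000693), a difference of −8.45 ± 1.06. Both effects also passed for Pax5 (2.13 and −3.69, difference −5.83 ± 0.99) and the sulfotransferase gene Chst3 (1.74 and −2.14, difference −3.88 ± 0.7). The rise over control was not in all T58A lymphomas: Pax5 and Chst3 were at 0.863 and 1.38 CPM in T58A lymphoma 3, and Fzd10 at 6.64 CPM in T58A lymphoma 1, below every control. Above control in T58A lymphomas, with an effect below 0 that did not pass in S62A lymphomas, were Serpina10 (−3.46 ± 0.76), Clu (−3.2 ± 0.35), Ltbp1 (−3.16 ± 0.52), Mef2c (−2.27 ± 0.37) and Plvap (−0.99 ± 0.21). Below control in S62A lymphomas, with an effect above 0 that did not pass in T58A lymphomas, were Ngp (−7.13 ± 1.21), Fcer2a (−6.11 ± 1.23), S100a8 (−5.23 ± 0.71), Fcrla (−3.49 ± 0.68) and Cplx2 (−1.71 ± 0.42). Above control in S62A lymphomas, with an effect below 0 that did not pass in T58A lymphomas, were Rfx4 (7.88 ± 1.66), Limch1 (3.28 ± 0.46), Eif5a2 (2.02 ± 0.38) and Tmem184c (1.52 ± 0.29). Dclk2 stood below control in T58A lymphomas (−2.96, adjusted p = 0.0039) and differed by 3.2 ± 0.63. Adjusted p-values of the direct differences ran from 0.00723 for Clu to 0.05 for Cplx2, which lay under the threshold before rounding.

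Single libraries ended the call or moved the fold by over 1.5 times for 10 of the genes given. The call of Dclk2 was lost without T58A lymphoma 2 (adjusted p = 0.0928), and its difference was 1.97 without S62A lymphoma 3. Tmem184c lost its call without T58A lymphoma 2 or 3 or S62A lymphoma 1 or 3 (differences of 1.34 or more, adjusted p up to 0.0887), as did Cplx2 (−1.43 or lower, adjusted p up to 0.147). Fcrla lost its call without T58A lymphoma 2 or any S62A lymphoma (−2.97 or lower, adjusted p up to 0.0772). Plvap lost it without T58A lymphoma 2 or S62A lymphoma 1 or 2 (−0.73 or lower, adjusted p up to 0.088), and Rfx4 without any T58A lymphoma or S62A lymphoma 3 (5.42 or higher, adjusted p up to 0.0985). All reads of Ngp in S62A lymphomas lay in the third and all 3 of Pax5 in the second, so without these libraries only a bound remains. Without S62A lymphoma 3, Limch1 was at 2.55 and S100a8 at −5.99, still called. For Chst3, Fcer2a and Serpina10 the direct difference was not rerun without single libraries.

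In splenomegaly masses B cell genes stood higher, and double-positive thymocyte and thymic epithelium genes lower, than in control. The double-positive fall did not rest on scaling or the 50 most abundant genes (median −6.4 with library size only and without them). B cell and epithelium lists were not rerun without them. A lower share of thymocytes alone would raise the markers of all other cell types alike, whereas the medians of B cell, thymic epithelium, macrophage, fibroblast and endothelium lists spanned 12.61 on the log2 scale, from −7.96 for thymic epithelium to 4.65 for B cells. Lymph node tissue in the masses may contribute: genes of lymph node stroma and high endothelium had medians of 2.85 against control (8 of 11 up, 9 adjusted over the list alone, adjusted p = 0.00428, and adjusted p = 0.295 with an estimated correlation) and 4.01 against S62A lymphomas (9 of 11 up, 9 adjusted over the list alone, adjusted p = 0.00162, and adjusted p = 0.285 with an estimated correlation). The differences that the labels name, B lymphocytes and endogenous MYC beside the mutant, were untested and stay open.

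Genes of B cells and granulocytes stood lower in S62A than in T58A lymphomas. Granulocyte RNA or reads carried over from splenomegaly libraries are argued against, since the granulocyte genes of T58A lymphomas 1, 2 and 3 had medians of 412%, 153% and 257% of their splenomegaly level. Other cells in the T58A libraries stay open. Of the 358 lower genes, 83% (297) were higher in splenomegaly masses than in S62A lymphomas. Both comparisons share the S62A libraries, so this decides nothing. For B cell genes, carry-over from splenomegaly libraries and B cells within the tumours cannot be told apart, because the excess over S62A lymphomas, as a percentage of that in splenomegaly masses, was 11.19, 17.58 and 0.45 for B cell genes and 4.12, 9.09 and −0.42 for plasma cell genes in T58A lymphomas 1, 2 and 3, with ratios of 0.37 and 0.52 in the first pair. A difference due to the mutant, or to the title code that goes with it, stays open and was untested.

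Each comparison of 3 against 3 libraries has 10 splits, of which 1, the real one, gave as many genes. That is too few splits for a share under 0.05. The real counts were 5646 for T58A lymphoma against control, 6885 for S62A lymphoma against control, 7681 for splenomegaly against control, 492 for S62A against T58A lymphoma and 8472 for splenomegaly against S62A lymphoma. The highest counts of other splits were 0, 1, 0, 12 and 0 in the same order.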

How the results depend on the processing

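The mean of a gene's transcripts, removal of Rn45s, removal of the 50 most abundant genes and removal of T58A lymphomas 1 and 2 together were chosen only after the data were seen. Counts of genes against control, and between splenomegaly masses and S62A lymphomas, stayed within 1.5 times the reported count, except T58A lymphomas against control with title code H only. That fit kept 1 control and called 1320 genes, with Myc at 0.79 (adjusted p = 0.0628), and the lone control is assumed to vary like the other groups. Leave-one-out counts ran from 3865 to 5123 for T58A lymphoma against control, 5115 to 6595 for S62A lymphoma, 6019 to 6726 for splenomegaly, and 7264 to 8223 for splenomegaly against S62A lymphoma. The 492 genes between the lymphoma groups became 1754 with DESeq2, 4 with limma voom (2374 at an unadjusted p under 0.05), 0 with edgeR on the 6 libraries only (2045 at an unadjusted p under 0.05), 313 on log2(FPKM + 1), 184 on log2(FPKM + 1) without a filter, and 319 without T58A lymphomas 1 and 2. Leave-one-out counts there ran from 139 without T58A lymphoma 2 to 783 without T58A lymphoma 1, with 267 without S62A lymphoma 2. Higher and lower genes there, 134 and 358, became 86 and 456 with library size only, and 81 and 472 when also without the 50 most abundant genes. Rises and falls on FPKM without a filter were 2539 and 3967 in T58A and 2511 and 4835 in S62A lymphoma against control, and with DESeq2 4539 and 4310 for splenomegaly against S62A lymphoma. Myc leave-one-out ranges were 0.71 to 0.82 in T58A lymphoma, 0.93 to 1.13 in S62A lymphoma and 0.12 to 0.25 in splenomegaly against control, 0.14 to 0.35 between the lymphoma groups, and −0.98 to −0.78 for splenomegaly against S62A lymphoma. Among 522 results for named genes, 10686 values under 28 settings comprised 9993 with the same call and direction, 691 that lost the call and 2 that reversed. Without 1 library the fold moved by over 1.5 times for 25 of 114, 37 of 121, 14 of 120, 15 of 46 and 32 of 121 named genes, in the order of the Myc ranges. The reversals were Ly6c2, a gene with near-identical relatives, from 1.55 to −0.22 in T58A lymphoma against control without T58A lymphomas 1 and 2, and Ucp1 in the same comparison, from −6.28 to a leave-one-out range of −6.96 to 0.08, the latter without control 3. Called lists numbered 91 of 180 (87 to 100 in leave-one-out), 97 with fry and 0 with camera at an estimated correlation. Of 3060 list values under 17 settings, 2793 were the same, 152 lost the call, 109 gained it and in 6 the direction of the list test turned. Without T58A lymphomas 1 and 2, B cell genes in T58A lymphoma against control turned to −0.95 (adjusted p = 0.00996), and between the lymphoma groups the direction of the test turned, without a call, for interferon response (median still below 0, −0.12, adjusted p = 0.604), mature T cell (0.3, adjusted p = 0.222), plasma cell and germinal centre (0.32, adjusted p = 0.775) and dendritic cell genes (0.04, adjusted p = 0.464). Pan T cell genes between the lymphoma groups ran from −0.32 to 0.24 in leave-one-out, reversed without S62A lymphoma 3. Fewer libraries lie behind the smaller counts of the title code H fit, and for the other changes the cause was not tested. Depth limits low genes most in splenomegaly 2, with 9577373 reads. Replicate numbers pair nothing, so no paired analysis was run.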

Other observations

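The test of adipose tissue in control 3 was chosen only after the result was seen, and the lists of Wnt targets, imprinted genes and unfolded protein response were drawn up after the data were examined. Genes of these lists are named here after their values were seen.

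In both lymphoma groups several inhibitors and targets of Wnt signalling stood far above control. Nkd1, an inhibitor that is itself induced by Wnt signals, rose from 2.98 ± 0.199 CPM (SD, n = 3) to 366 ± 156 in T58A and 569 ± 76.8 in S62A lymphomas, and was at 1.56 ± 0.811 in splenomegaly masses. Axin2, a scaffold of the complex that degrades beta-catenin, rose from 30.4 ± 2.65 to 319 ± 45.1 and 311 ± 101 CPM (log2 fold changes 3.39 ± 0.22 and 3.36 ± 0.22, adjusted p = 3.98e-06 and 3.07e-06). The stem cell receptor gene Lgr5 rose by 6.74 ± 0.93 and 6.36 ± 0.92 (adjusted p = 0.000335 and 0.00033). The T cell factor gene Lef1 did not pass, at −0.31 ± 0.39 in each group (adjusted p = 0.566 and 0.546).

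Chaperones of the endoplasmic reticulum and other genes of the unfolded protein response stood higher in splenomegaly masses. Hspa5, the chaperone BiP, rose from 325 ± 12.5 CPM in control tissue to 3640 ± 869 (3.48 ± 0.2, adjusted p = 1.05e-06), against 736 ± 122 in T58A and 686 ± 59.8 in S62A lymphomas. Xbp1, a transcription factor of secretory cells, rose from 174 ± 28.5 to 2890 ± 844 CPM (4.06 ± 0.42, adjusted p = 2.7e-05). Ddit3, a stress factor that promotes cell death, did not pass (−0.46 ± 0.25, adjusted p = 0.141).

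Higher Wnt and beta-catenin output in the lymphomas is a hypothesis. It was tested on 14 targets other than those in which the pattern was seen, of which 7 rose in T58A lymphomas (7 adjusted over the list alone) and 5 rose and 1 fell in S62A lymphomas (6 and 1 adjusted over the list alone). The medians were 0.8 and 0.46 (camera, adjusted p = 0.00428 and 0.0166, and adjusted p = 0.295 and 0.351 with an estimated correlation), so the calls may rest on genes that vary together. Against S62A lymphomas the list was lower in splenomegaly masses, with 9 of 14 down and 3 up (9 and 4 adjusted over the list alone) and a median of −2.99 (adjusted p = 0.000153, and adjusted p = 0.22 with an estimated correlation). Between the lymphoma groups the median was −0.19 (adjusted p = 0.721). A change in cell types was not separated from a change per cell.

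A secretory programme of plasma cells in splenomegaly masses is a further hypothesis, drawn from Jchain, Mzb1 and Derl3, none of which, nor Xbp1, is in the list tested. Of 23 genes of the unfolded protein response 22 rose against control and 19 were higher than in S62A lymphomas (22 and 19 adjusted over the list alone), with medians of 2.52 and 2.19 (camera, adjusted p = 2.25e-27 and 1.2e-16, and adjusted p = 0.0699 and 0.195 with an estimated correlation). The list also rose in T58A lymphomas, with 16 up and 2 down (16 and 2 adjusted over the list alone) and a median of 0.64 (adjusted p = 0.00162, and adjusted p = 0.479 with an estimated correlation). In S62A lymphomas 9 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.53 (adjusted p = 0.014, and adjusted p = 0.577 with an estimated correlation). These values are consistent with the hypothesis for splenomegaly masses, where the lower median was 2.19.

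Imprinted genes were not raised as a group. H19 stood at 5790, 741 and 989 CPM in T58A lymphomas 1, 2 and 3 and at 213, 549 and 4730 CPM in S62A lymphomas 1, 2 and 3, against 48.1 ± 18.3 in controls, and Igf2 at 1490, 50.4 and 115 CPM and 21.3, 22.8 and 388 CPM, against 3.71 ± 0.498. Of 14 other imprinted genes 2 rose and 2 fell in T58A lymphomas and 2 rose and 2 fell in S62A lymphomas (2 and 2, 1 and 2 adjusted over the list alone), with medians of −0.28 and −0.45 (adjusted p = 0.721 and 0.506).

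Control 3 stood apart from controls 1 and 2 in adipocyte genes and ribosomal RNA. All 16 adipocyte genes (100%) were over 2 times as high as the mean of controls 1 and 2, with a median ratio of 12.1, and Ucp1, the uncoupling protein of brown fat, was at 245 CPM against 1.75 and 0.22. Adipose tissue in that library is a candidate explanation, and no other was tested. Rn45s, a ribosomal RNA precursor, took 2.308% of its reads, against 0.142% to 0.268% in the other libraries. Without Rn45s the number of genes called between S62A lymphomas and controls moved by 0.16%.

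The labels used here give no sex, and genes of the sex chromosomes differed within every group but the controls. Xist, expressed from the inactive X chromosome, was at 4.9, 2.92 and 2.6 CPM in controls 1, 2 and 3, at 1290, 61.8 and 44.8 CPM in T58A lymphomas, at 1.15, 0.934 and 2260 CPM in S62A lymphomas and at 780, 38 and 1010 CPM in splenomegaly masses. Ddx3y, on the Y chromosome, was at 143, 151 and 156 CPM, at 6.24, 154 and 158 CPM, at 228, 201 and 1.73 CPM, and at 0.106, 122 and 10.2 CPM in the same order. T58A lymphoma 1 and splenomegaly 3 thus held much Xist with some Ddx3y, and T58A lymphomas 2 and 3 and splenomegaly 2 held much Ddx3y with Xist at 61.8, 44.8 and 38 CPM, above the 0.934 to 4.9 CPM of controls and S62A lymphomas 1 and 2. Mixed material and reads assigned to the wrong library were not tested with these genes. Both stay open for these 5 libraries, and with them the origin of the B cell RNA in T58A lymphomas.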
